A study of Arabidopsis thaliana with 12 samples.

How the data were processed

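Transcript levels were measured on 12 arrays of Arabidopsis thaliana, ecotype Landsberg, 6 from the flu mutant and 6 from the wild type (WT), all after 12 h of darkness. The flu mutant is mutated in FLU, a negative regulator of chlorophyll synthesis. Tissue, array platform, hybridisation, scanning and scaling are not given in the sources used here. The labels do not say whether arrays came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical.

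The deposited table held a linear intensity for 3439 features on each array, with values from 0 to an upper limit of about 100 that was reached on every array. How the authors scaled the intensities and what set the limit is unknown. Array medians lay between 0.443 and 0.491 in WT and between 0.426 and 0.442 in flu, and each array listed 108 to 165 features at exactly 0. The number of arrays limits the precision, and background readings were not analysed here. A platform table listed 1562 of the features. Of these, 692 had exactly 1 gene, 870 had several and were not named, and 1877 features were unlisted and stay unnamed here. Symbols were updated through gene identifiers from the RefSeq table of assembly TAIR10.1, which matched 690 of the 692 features. No coordinates are given, because the build behind the array was not named. No feature was listed for FLU, so the mutated gene was not analysed here and did not check the labels.

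Values below the 1st percentile of the positive values (0.0236) were raised to it, log2 transformed and quantile normalised, since the array medians differed. Fold changes are on this scale. The floor limits the falls of the dimmest features, and normalisation raised the log2 change by a median of 0.38 in the dimmest 860 features and 0.07 in the brightest 860, so rises of dim features are larger than as deposited. The planned comparison, flu minus WT over 12 arrays with no block, used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p below 0.05). A gene counts as measured where a feature lists it alone. Gene lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01. The directional test of fry was an alternative, and its mixed test, added after the results were seen, passed most random lists and is not used. The planned design, the alternatives, 21 gene lists and the naming rule were fixed before the data were examined. The rule named the 10 highest and 10 lowest changes among passing features with 1 gene, with at least 5 flu arrays beyond the WT mean, and up to 3 passing members per list with the largest absolute change.

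Further choices were made after seeing the data. Arrays 1 and 2, 3 and 4, and 5 and 6 of each genotype, called couples here, resembled each other, with Spearman correlations of 0.909 to 0.967. Couples of WT correlated at 0.780 to 0.872 with each other, couples of flu at 0.893 to 0.942, which overlaps the range within couples. Couples are not named in the labels. The difference between genotypes also followed the feature number, in 48 strips of 6 numbers that recur with a period of 288. That period was taken as the best of 11 tried and that width as the best of 5. One added analysis therefore averaged each couple (n = 3 per genotype), and another also subtracted from each array the mean deviation of each strip. Changes are called risen or fallen where they passed in all 3 analyses with the same sign. Means and SDs are of deposited intensities over 3 couple means. A further 7 gene lists were written after fits had been seen, some of their members' values included, and are not independent evidence.

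The fits were tested on simulated data with the measured spread, 3439 features and 200 true changes, in 5 runs. With WT and flu arrays deviating independently and no position effect, 39.6% of the features passing over 12 arrays were false, against 5.10% with couples averaged and 5.39% with strips centred too. With the observed strip pattern added as an unwanted shift, these shares were 90.4%, 74.7% and 6.74%, and the last analysis recovered 1.79%, 30.8% and 77.6% of changes of 0.5, 1 and 2 on the log2 scale. With same-numbered WT and flu arrays sharing 47.8% of the variance between couples and 43.6% of that within couples, as estimated from the data, the shares of false passes were 12.7%, 1.31% and 1.08% without a position effect and 89.5%, 58.8% and 0% with it. Wherever the strip pattern was added, it had the same 48 strips that centring removes. The low false shares with strips centred were thus largely built in, and do not cover a position effect of another shape. In simulated data without change or shared deviations, camera passed 3% of 200 random lists at an unadjusted p below 0.05.

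Replicate numbers were checked for pairing across genotypes. Deviations of same-numbered WT and flu arrays from their group means correlated at 0.368 to 0.539, and 12 of 12 arrays correlated best with their own number, so the numbers pair the arrays. This pairing comes from the data, not from the labels. Alternatives covered the scaling, the offset, filters on dim features, the replicate number as a block, moderation, array weights, an exact permutation test, left-out arrays, and those added after seeing the data.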

Results

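The 12 arrays compared the dark-treated flu mutant with the WT, 6 arrays each, over 3439 features. The comparison asks which transcripts differ in the dark between flu mutant and WT plants. The first principal component held 47.1% of the variance and separated the genotypes.

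AT3G52960, the plastid type II peroxiredoxin, rose from 0.299 ± 0.0926 in WT to 1.19 ± 0.215 in flu (SD, n = 3 couple means), a log2 change of 2.21. AT5G44000, of the glutathione S-transferase family, rose by 2.21 on the log2 scale (1.72 as deposited), and Cpn60beta4 (AT1G26230), a plastid chaperonin subunit, by 2.06 (1.51 as deposited). AT3G23940, the dihydroxyacid dehydratase of branched-chain amino acid synthesis, rose from 0.337 ± 0.0498 to 1.83 ± 0.328 (n = 3), and AT5G46390, a C-terminal processing peptidase, rose from 0.210 ± 0.0460 to 1.02 ± 0.198 (n = 3). The highest change was that of AT4G35660, from 0.390 ± 0.121 to 8.95 ± 2.58 (n = 3), or 4.65 on the log2 scale (limma adjusted p = 1.3e-07 over 12 arrays and 0.0022 with couples averaged).

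The other 4 of the 10 highest were AT4G31930, of a mitochondrial glycoprotein family, at a log2 change of 3.10, AT3G25680 at 2.98, AT4G09040 at 2.33 and AT2G30100 at 2.25. All 10 rose in the 3 analyses, at 1.67 to 4.18 with strips centred, and all were higher in 6 of 6 flu arrays. AT4G31930 depended on the WT couples. Its log2 change was 3.90 without WT arrays 3 and 4 and 2.13 without WT arrays 5 and 6, and its adjusted p with couples averaged was 0.048.

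Among the 10 lowest changes, 7 fell in all 3 analyses, at -3.21 to -1.16 with strips centred. AT1G03810 fell from 6.15 ± 1.44 in WT to 1.16 ± 0.166 in flu (n = 3), a log2 change of -2.34. AT1G76450, of the photosystem II PsbP family, fell from 0.552 ± 0.0760 to 0.125 ± 0.0420 (n = 3), and AT3G45770, a mitochondrial enoyl reductase, fell from 0.284 ± 0.107 to 0.0551 ± 0.0258 (n = 3). AT5G38360 had the lowest value, -2.71. Of its 6 flu arrays 4, and its flu mean, lay below the floor (2 arrays listed at 0), so the floor limits the size of its fall. It was also the lowest of the 10 as deposited (-3.16) and with strips centred (-3.21). With the offset it stood at -2.30, against -2.31 for AT1G03810, and with array weights at -2.66, against -2.70 for AT2G27680. A further 7 of the 10 lowest had 1 or 2 flu arrays below the floor. AT1G24530 fell by 1.99, AT1G70350 by 1.83 and AT5G27860 by 1.82 on the log2 scale, the last with 1 flu array listed at 0. With strips centred their values were -1.58, -1.16 and -2.13. AT2G27680, an aldo-keto reductase, AT4G22490 and AT1G78790 had log2 values of -2.25, -2.15 and -1.80 over 12 arrays, and of -1.80, -1.48 and -1.21 with couples averaged and strips centred, where adjusted p was 0.068, 0.053 and 0.065. AT2G27680 had an adjusted p of 0.0505 with couples averaged alone, and stood at -1.56 without flu arrays 3 and 4.

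**Figure D1:**
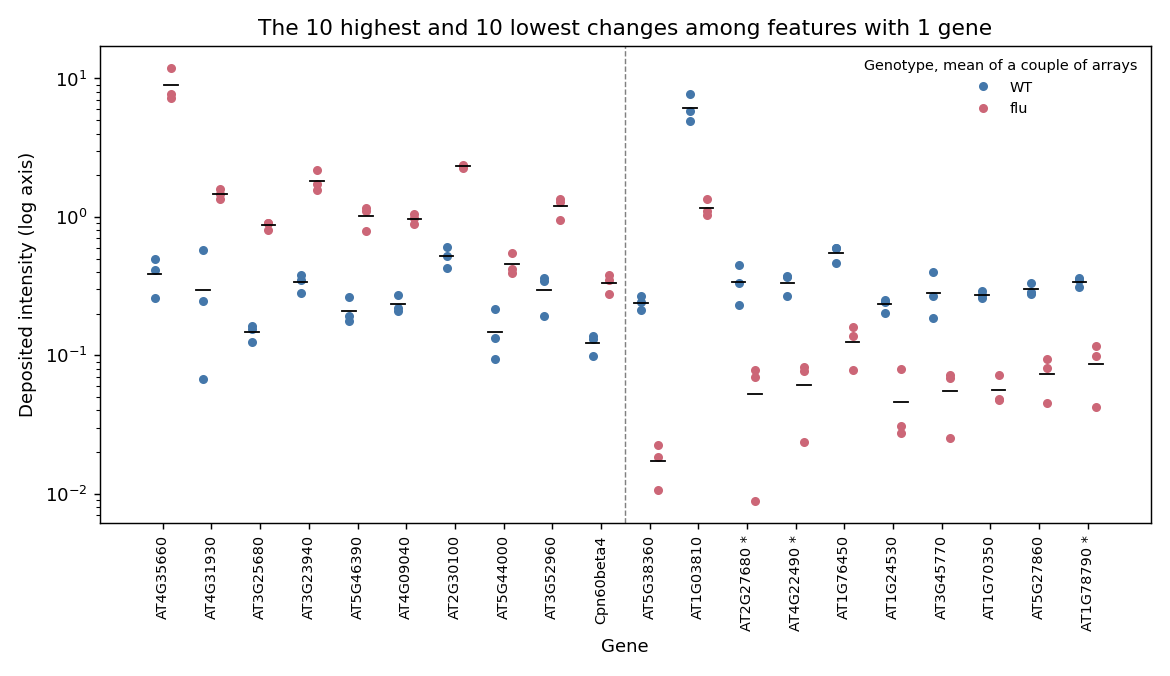
Deposited intensity (log axis) of the 10 highest and 10 lowest changes among features with 1 gene, with points for the mean of each couple of arrays, black lines for the mean of the 3 couples, WT in blue and flu in red. An asterisk marks the 3 genes that did not pass in all 3 analyses, and AT4G35660 shows the widest gap, 0.390 in WT against 8.95 in flu.

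Across the array, 1796 of 3439 features passed over 12 arrays (791 higher and 1005 lower in flu), 1193 with couples averaged (500 and 693) and 956 with strips centred too (469 and 487). In all 3 analyses 313 features rose and 351 fell, and among the 692 features with 1 gene 59 rose and 79 fell. In simulated data with 200 true changes, like couples and no position effect, 39.6% of the passes over 12 arrays were false when same-numbered WT and flu arrays deviated independently, and 12.7% when they shared deviations as observed. With the observed strip pattern added these shares were 90.4% and 89.5%, where the whole strip pattern counts as false. A false share depends on how many features truly change, so none of these shares is an estimate for the 1796 features. Of the 1796 features, 606 did not pass with couples averaged and 1000 not with strips centred too, and centring turned the sign of 99. Strips with a negative mean difference held 48.6% of the features, but 82.8% of the lower and 21.5% of the higher calls. The strips were sorted by the same log2 changes that made the calls, so part of this gathering is built in. Strips of neighbouring feature numbers differed in mean log2 change from -0.67 to 0.61.

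**Figure D2:**
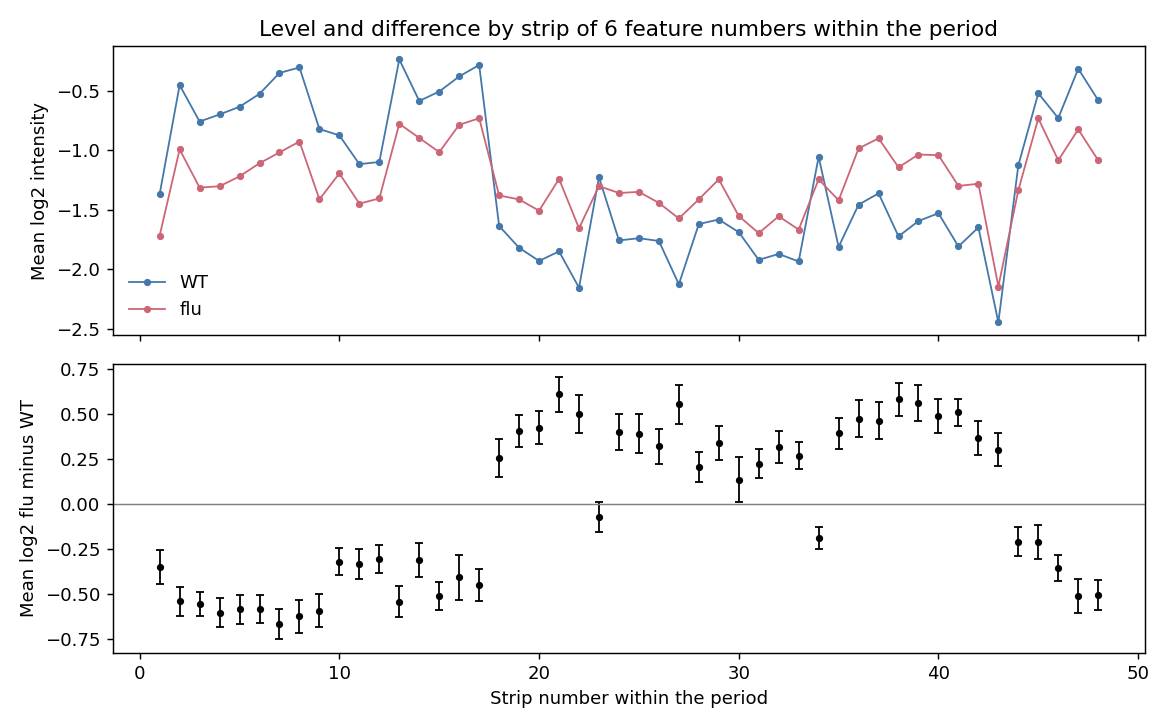
Mean log2 intensity of WT (blue) and flu (red) in each of 48 strips of 6 feature numbers (upper panel), and the mean log2 difference flu minus WT with its standard error over 63 to 80 features a strip (lower panel). Mean differences run from -0.67 to 0.61, and WT strips spread more (SD 0.622) than flu strips (SD 0.296).

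Photosynthesis and chlorophyll genes were measured by few features with 1 gene, and 1 of the 8, PRK, passed over 12 arrays. Of all 692 features with 1 gene, 49.7% passed. LHB1B2, a light-harvesting protein, stood at 17.5 ± 2.66 in WT and 18.4 ± 1.4 in flu (n = 3), PSAN of photosystem I at 6.55 ± 1.79 and 5.77 ± 0.582 (n = 3), and PSBW of photosystem II at 16.8 ± 3.07 and 20.4 ± 1.18 (n = 3). None of these, nor PSBY, SBPASE of the Calvin-Benson cycle, CHLM of chlorophyll synthesis or AT1G74470, the geranylgeranyl reductase, passed over 12 arrays. With strips centred, PSBW and SBPASE passed as higher, at 0.59 and 0.84 on the log2 scale. PSBW, SBPASE, LHB1B2 and CHLM all lay in strip 13, whose mean log2 change was -0.54. Centring raised them by the same amount, so their centred values are not separate evidence. LHB1B2 had opposite directions, higher in flu by its deposited means, but at -0.26 after normalisation over 12 arrays and at 0.28 with strips centred, with adjusted p of 0.078, 0.24 with couples averaged and 0.35 with strips centred too. PRK (AT1G32060), phosphoribulokinase, had a log2 value of -0.73 (limma adjusted p = 0.017, and 0.0028 with the replicate block). With couples averaged its adjusted p was 0.14, or 0.047 with couple number as a block, and with strips centred too its value was -0.38 (adjusted p = 0.38). It stood at -0.42 (adjusted p = 0.051) without WT arrays 5 and 6, -0.72 (0.055) without flu arrays 1 and 2 and -0.58 (0.095) without flu arrays 3 and 4.

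Of the 21 fixed lists, 7 held a measured gene and 14, among them the root markers, seed markers and reference genes, held none. The 870 features with several genes and the 1877 unlisted ones were not matched to lists. Further list members may be among them. Among 6 measured plastid ribosomal proteins, 1 was higher and 3 were lower over 12 arrays, where 49.7% of all features with 1 gene passed. Adjusted over the list alone, 4 of the 6 passed. These 6 include AT5G65220, which was listed at 0 on 5 WT and 6 flu arrays and so could not show a fall. AT4G01310 rose from 0.352 ± 0.0408 to 0.646 ± 0.0196 (n = 3) and was the member that passed in all 3 analyses. AT3G54210 stood at -0.71 on the log2 scale, and at -0.17 (limma adjusted p = 0.47) with couples averaged and strips centred. AT3G13120 and AT1G64510 stood at -0.61 and -0.51, with adjusted p of 0.053 and 0.054 with couples averaged and no block, and with strips centred too both passed as lower at larger log2 values (adjusted p = 0.0073 and 0.014), AT1G64510 at -1.01. With the replicate block over 12 arrays, AT3G13120 had a limma adjusted p of 0.019. As a list they did not pass camera (adjusted p = 0.993, also with an estimated correlation). The antioxidant list held AT3G52960 alone, which passed adjusted over the list alone too. Adjusted over the list alone in the 12-array fit, LHB1B2, the 1 measured antenna gene, passed as lower (limma adjusted p = 0.044, over a list of 1), a direction that its deposited means and its value with strips centred did not share. PRK passed as lower and SBPASE as higher in the Calvin-Benson list, and the 2 photosystem lists and the chlorophyll list had no pass.

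The 7 lists written after fits had been seen are described without independence. For scale, 49.7% of all features with 1 gene passed over 12 arrays and 19.9% in all 3 analyses. The member counts of these lists include CCB3 (thylakoid assembly), AT1G66090 (stress and immune) and IAA31 (reproductive and meristem). Each of these was listed at 0 on 5 or 6 arrays of each genotype. In the redox list, 3 of 8 members were higher and 3 lower, and GLDH, the last enzyme of ascorbate synthesis, fell from 0.963 ± 0.0229 to 0.360 ± 0.0403 (n = 3), a log2 change of -1.31, or -0.76 with strips centred. The NADP-dependent malate dehydrogenase AT5G58330 stood at 0.884 ± 0.439 in WT and 2.01 ± 0.233 in flu (n = 3), with a limma adjusted p of 0.0027 over 12 arrays with or without the replicate block, 0.064 with couples averaged, and 0.035 with strips centred too, at a log2 value of 1.14. Of 13 thylakoid assembly genes, 2 were higher and 2 lower, and CRR41 rose by 1.49 on the log2 scale, or 1.22 with strips centred. LPA19 stood at -1.14, but at -0.48 (adjusted p = 0.058) with strips centred. CRR21 (AT5G55740) stood at 0.74, with an adjusted p of 0.033 that became 0.158 with couples averaged and 0.497 with strips centred too, where the log2 value was 0.28. Its adjusted p was 0.065 with the replicate block and 0.055 to 0.071 without WT array 2, 5 or 6 or flu array 1, 2, 5 or 6.

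Of 22 organelle RNA factors, 5 were higher and 5 lower. AT3G46950 fell by 1.28, or 0.74 with strips centred. AT3G22150 and AT5G39980 had values of 1.38 and 1.22, and of 0.80 and 0.85 with strips centred (adjusted p = 0.115 and 0.118), and AT5G39980 did not pass with couples averaged either (0.079). Of 10 stress and immune genes, 3 were higher and 3 lower, DI21 fell by 1.38, and AT1G35210 and CML41 rose by 1.25 and 0.91, or -0.94, 0.83 and 1.42 with strips centred. The 7 reproductive and meristem regulators were listed as markers of another tissue, but the tissue used is not given. Over 12 arrays 1 was higher and 2 lower, with LAS at -1.30, SPL at 0.91 and AGL26 at -0.55. With strips centred these values were -0.70, 0.59 and -0.01. In all 3 analyses 0 of the 7 passed, against 19.9% of all features with 1 gene, but 7 members are few for such a comparison. The 4 widened tetrapyrrole genes had no pass, and the 6 genes of the joined photosynthesis list had 1, PRK. No list passed camera (adjusted p = 0.993 for each, 0.975 to 0.988 with couples averaged and 0.291 to 0.636 with strips centred too). The mixed test of fry, for change in either direction, passed 62.9% to 100% of 1000 random lists of the same sizes over 12 arrays, so its passes are not read. Median, mean and camera direction differed in sign for the joined photosynthesis list (-0.01, -0.09, higher), the tetrapyrrole list (-0.01, -0.04, higher) and the redox list (-0.13, 0.37, higher). With couples averaged and strips centred their medians were 0.52, 0.37 and 0.33. LHB1B2, PSBW and SBPASE of the photosynthesis list and CHLM of the tetrapyrrole list share a strip, so centring moved them together.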

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

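A single array stood far from the other 5 of its genotype in 5 of 82 groups tested, against 4.1 taken as the chance count. That count is a flat share of the groups and does not allow for the resemblance of arrays within couples. On the normalised log2 scale, AT1G78790 was at -5.41 in flu array 2, against -3.53 to -2.43 in the others. Its deposited value there, 0.0218, lay below the floor of 0.0236, so the flagged value is set by the floor. AT1G51100 (CRR41) was at -0.13 in flu array 5, against -0.51 to -0.38. AT1G05385 (LPA19) was at -1.79 in flu array 1, against -1.61 to -1.50. AT4G27330 (SPL) was at -1.33 in flu array 1, against -0.82 to -0.58. WT array 2 listed 108 features at 0, against 123 to 131 in the other WT arrays.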

How the results depend on the processing

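The couple, strip, left-out-couple and mixed fry analyses, the filter on zeros and the comparison among features with 1 gene were chosen after seeing the data. Among the 1720 features above the median intensity 1084 passed, a larger share than the 1796 of all 3439. The count of 1796 became 806 with an absolute log2 change of at least 1. With couples averaged it was 1193, with strips centred too 956, and with these and the replicate block 1177. Taken singly, centring gave 1697 (1184 shared with the 1796) and the couple as a random term 1369, and couples averaged with the block gave 1306. It was 1966 with the replicate block alone, and between 1539 and 1875 with arrays or couples left out. Values as deposited gave 1912, with 34.0% higher against 44.0%, and a median over all features of -0.20 against -0.04. Among the 37 named genes, 1493 alternative values kept direction and side of the threshold, 65 (16 genes) lost the threshold, and none reversed; apart from CRR21, the replicate block changed no named call. The plastid ribosomal list passed no directional alternative when adjusted over the 8 tested lists. Its unadjusted p with directional fry was 0.048, just below 0.05. It was the 1 tested list fixed before the data were examined, and the 7 others were written after fits had been seen. The lack of a pass with fry therefore depends on adjusting together with those 7 lists. Directions of camera or directional fry turned, without a pass, for joined photosynthesis genes with the offset (adjusted p = 0.987), the replicate block (0.966), couples averaged with the block (0.967), among features with 1 gene (0.953), with fry (0.551), and with WT arrays 3 and 4 (0.887), WT arrays 5 and 6 (0.930) or flu arrays 3 and 4 (0.899) left out; without WT 4, WT 6, flu 3, flu 4 or flu 6 it turned too (0.904 to 0.987), and over all single arrays left out p ran from 0.865 to 0.995. They also turned for redox (0.109) and organelle RNA lists (0.106) with fry; tetrapyrrole genes without WT arrays 3 and 4 (0.887); reproductive genes without WT arrays 1 and 2 (0.999). The cause of these turns was not tested. Signal over background was not analysed here.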

Other observations

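All tests in this part were chosen after the results were seen. Beside the genotype, the first couple of arrays stood apart. In a limma fit on couple means with genotype as a term, 20 features were lower in the first couple than in the others and 0 higher (580 at an unadjusted p below 0.05). The 7 with 1 gene were AT4G04370, listed at 0 in the first couple of both genotypes, NdhN, a subunit of the thylakoid NDH complex (0.422 in WT and 0.480 in flu, against 1.27 to 1.57 in the other couples), UGT74D1, AT2G41120, AT1G76240, AT5G09820 and AT1G68430. The same fit gave 2 features for the second couple (207 unadjusted) and 0 for the third (212 unadjusted).

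The difference between genotypes followed the feature number with a period of 288. Strips explained 23.6% of the variance of log2 change, against at most 0.856% in 1000 shuffles, which leave out the choice of period and width. Spot position or source plate is a candidate explanation, as strip means of even and odd sets of 288 numbers correlated at r = 0.931 (permutation p = 1e-04, the smallest possible), and strips also explained 4.48% to 14.7% of differences between couples of 1 genotype. Period and width were chosen on the log2 changes of both sets, so the correlation between the sets is in part built in. One order of genes along the numbers is argued against, since sets of 288 explained 0.927%. A difference in transcripts stays open: over 92 pairs of features listed for the same genes, differences in log2 change followed strips (r = 0.384, across features, permutation p = 6e-04), but the pairs' own changes correlated at 0.088, so they may be different paralogs and the test decides nothing.

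Arrays 1 and 2, 3 and 4, and 5 and 6 resembled each other. A candidate explanation is that each couple is a pair of readings of 1 hybridisation or 1 RNA sample, with a consensus correlation of 0.554 around the group means. Flu arrays 5 and 6 are the exception, with deviations correlating at -0.048. No biological explanation was tested.

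Same-numbered WT and flu arrays deviated together. The same spots or membrane read for both genotypes is a candidate explanation, since the lowest same-number correlation exceeded the highest with the other array of the couple by 0.107. Plants of a shared harvest cannot be told apart from it, because a harvest could also follow the number. The mean correlation with the other array of the couple was 0.145, between 0.460 for the same number and -0.149 for other couples.

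The count over 12 arrays was reached by 1 of 100 splits drawn from 462, the real one, with 1796 features against at most 5 in the others, and at most 0 in the 8 that parted all 6 numbers. These splits treat the arrays as exchangeable, which the couples are not, so they do not exclude chance at the level of couples. With couples averaged, 10 splits are too few for a share under 0.05, with 1193 features in the real split and at most 0 in the others, and 956 against at most 0 with strips centred too.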
